A study of Mus musculus with 6 samples.

How the data were processed

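Gene expression was measured in mouse Treg cells of 2 genotypes, Batf+/+ and Batf-/-, with 3 arrays each. Per the labels, the cells were CD4+ and carried human CD2 expressed with Foxp3, came from lymph node and spleen of C57BL/6 mice and were not cultured. Total RNA was labelled with biotin by a kit that primes at the 3' end and hybridised to a 3' expression array, per the labels' protocols. The labels call the populations triplicates but do not say whether each came from a different mouse, so the p-values measure the spread between these samples, which may be partly technical.

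The deposited values, taken here as log2 values, were made by the authors with RMA, per the submitters' processing notes, which give no version and no log base. RMA corrects background, normalizes arrays to common quantiles and summarises the probes of a probe set on the log2 scale. The values show a further step that no label describes: in each of the 45101 probe sets the middle value of the 3 Batf+/+ arrays is exactly 0, so every probe set was set relative to the median of the Batf+/+ arrays. The log base was therefore an assumption here, taken as 2, as RMA gives it. The lowest value, -4.96, would be too large a span in base 10 for a scanner of 16 bits. Centring does not alter differences between genotypes, but it removes absolute levels, so dim genes could not be told from bright ones and signal over background is not known. It also makes the spread of values over all genes narrower on the Batf+/+ arrays than on the Batf-/- arrays. Scan date and slide were not used here.

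Probe sets were named through the platform annotation: 34945 had 1 gene, 932 had several, 9160 had none listed and 64 were controls. Of the probe sets with 1 gene, 34741 matched a table of mouse genes by Entrez identifier, and 0 symbols needed an update. Control probe sets and those with several genes or none were left out of the comparison by gene. The plan, fixed before the data were examined, was to represent a gene by its probe set with the highest mean level, with the mean of its probe sets as the fallback for centred values. The fallback was used, and 9010 of the 18193 genes had over 1 probe set. Among the named genes 0 had probe sets of opposite direction at an unadjusted p below 0.05. No filter on low values was applied.

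Genotypes were compared by limma 3.58.1 in R 4.3.3 with lmFit and eBayes, with genotype as the only term and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p below 0.05, and fold changes are 2 to the power of the log2 difference. Lists of genes were tested by camera with its preset correlation of 0.01, adjusted over 31 lists, and again with an estimated correlation and by fry, which asks whether the members of a list move on balance in 1 direction and does not compare them with other genes. Members of each list were also adjusted over the list alone. The lists were fixed from textbook knowledge before the data were examined: Treg states (tissue, effector, resting, core identity), helper lineages, AP-1 and IRF factors, trafficking, TNF receptor and NF-kB, T cell receptor response, cell cycle, interferon, apoptosis, glycolysis, cholesterol synthesis, markers of 11 other cell types, dissociation stress, housekeeping and sex-linked genes. Median and mean differ in sign in 3 lists, AP-1 and IRF factors, NK cell markers and CD8 T cell markers, and the median differs in sign from the camera direction in the last 2 of them. Measures of single arrays were compared by exact two-sided permutation tests, with Benjamini-Hochberg adjusted p values of 1 for all 5 measures. One of them, the array median, was 0 with an SD of 0 in Batf+/+ arrays, which follows from the centring, so its test carries little information.

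The named genes follow a rule fixed before the data were examined. They are Batf, the 12 genes with the largest increase and the 12 with the largest decrease among called genes whose arrays do not overlap between genotypes (leaving out receptor segments, sex-linked genes and clone names), up to 4 called members of each list with the smallest adjusted p, and 16 genes fixed whatever their values, of which 14 are reported here. This gave 53 genes, 43 of them called. Any other gene is said to be named after its value was seen.

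The same numbers occur in the sample titles of both genotypes, and nothing in the labels says what they share. Deviations of same-numbered arrays from their group means correlated across genes at 0.407, 0.154 and 0.413, each above the minimum of 0.1 set beforehand, so the numbers were taken to pair the arrays on the basis of the values. These correlations are not independent, since they share the same group means. Across the spike-in controls the arrays numbered 3 matched (0.934). Numbers 1 and 2 were hardly told apart there, at 0.855 and 0.892 within a number and 0.761 and 0.854 across them. The fit without the number remained the main one, and the fit with it as a replicate block was run beside it. All 6 arrays were different, with at most 0.206% of values identical between any pair.

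The alternatives fixed beforehand were quantile normalization, equal array medians, every probe set tested on its own, probe sets with the suffixes _x_at and _s_at left out, array weights, the replicate block and leaving out each array in turn. Quantile normalization was applied to the centred values, whose spread over genes is narrower on the Batf+/+ arrays, so it shrinks differences in part by construction wherever it is given below. Robust variance without a trend, camera with array weights, and the count of neighbouring pairs in each alternative were added after the data had been seen. Genes near Batf were found from the gene order of the GRCm38.p6 table and set against 10000 random lists not matched on level.

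The procedures were tested on simulated data with the spread of these arrays over 18193 genes and 200 genes changed, in 5 runs. Recovery was 49.3% of genes changed by 0.5 on the log2 scale, 89.6% of those changed by 1 and 99.7% of those changed by 2, and 4.34% of calls were false. A list shifted by -0.3 was called in 5 of 5 runs and 0 other lists were called. Genes and arrays were simulated as independent, while estimated correlations within the real lists reached 0.60 for the interferon response and 0.62 for dissociation stress. These runs therefore do not give the rate of false calls of genes or lists in the real data.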

Results

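Regulatory T (Treg) cells restrain immune responses and are defined by the transcription factor Foxp3. The study asked how their transcriptome differs without Batf, a transcription factor of the AP-1 family that pairs with Jun proteins and acts together with Irf4. Treg cells were isolated as CD4+ cells carrying a human CD2 reporter of Foxp3 from lymph node and spleen of C57BL/6 mice, and their RNA was measured without culture on 3 arrays from Batf+/+ mice and 3 arrays from Batf-/- mice. Levels of 18193 genes were compared between the genotypes. All levels are log2 values relative to the median of the Batf+/+ arrays, so they give differences between genotypes for a gene and not how abundant its transcript was. The number of arrays limits the precision of every value.

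Batf itself was 7.43-fold lower in Batf-/- Treg cells, with a log2 difference of -2.89 ± 0.19 (SE, n = 3 arrays per genotype, limma adjusted p = 0.000202). Its mean level was 0.01 ± 0.14 (SD, n = 3) in Batf+/+ cells and -2.89 ± 0.45 (SD, n = 3) in Batf-/- cells, with -3.13, -3.16 and -2.37 on Batf-/- arrays 1, 2 and 3. Its 1 probe set therefore followed the genotype labels on all 6 arrays. After quantile normalization its log2 difference was -2.02, still past the threshold. Whether that probe set lies in the deleted part of the gene was not analysed here.

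More genes were lower than higher in Batf-/- Treg cells, and of the 43 measured members of the effector and tissue Treg lists 15 fell and 2 rose. The S100 proteins S100a4 and S100a6, the homing molecules Gpr15 and Itgae, the cytotoxic protease Gzmb and the receptor Klrg1 were among the genes with the largest decreases, while the nuclear receptors Vdr and Pparg were among those with the largest increases. In all, 208 of the 18193 genes changed, 151 of them lower (72.6%) and 57 higher in Batf-/- cells. A change of at least 2-fold was reached by 64 of these genes, 48 lower and 16 higher. In each of the 208 genes all 3 Batf-/- arrays lay on the same side of all 3 Batf+/+ arrays, a separation found in 2191 of all 18193 genes and given by chance in 10% of them. The median log2 difference over all genes was 0.0047. Quantile normalization gave 81 genes (58 lower and 23 higher), 79 of them among the 208. It puts the Batf-/- arrays and the centred Batf+/+ arrays, narrower by construction, onto the same distribution. Its smaller differences follow in part from that, and calls lost after it cannot be read apart from it. The replicate block raised the number of higher genes to 91. Without Batf+/+ array 1 there were 109 genes (78 lower and 31 higher) and without Batf+/+ array 2 there were 105 (73 and 32). In turn, 32 were higher without Batf+/+ array 3, 36 were higher without Batf-/- array 1 and 94 were lower without Batf-/- array 2.

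The 12 genes with the largest decreases fell between 3.37-fold and 12.5-fold and included Batf. S100a4, a calcium-binding protein linked to cell motility, was 12.5-fold lower (log2 difference -3.64 ± 0.20 SE, limma adjusted p = 9.7e-05), and the related S100a6 was 7.82-fold lower. Gpr15, a receptor that guides T cells to the large intestine, was 10.9-fold lower (-3.45 ± 0.16, adjusted p = 5.29e-05). Itgae, which encodes the CD103 integrin chain that binds E-cadherin on epithelium, was 9.13-fold lower (-3.19 ± 0.15, adjusted p = 5.29e-05). Gzmb, the protease granzyme B, was 4.02-fold lower with the smallest adjusted p of all genes (-2.01 ± 0.08, adjusted p = 4.08e-05), and Klrg1, an inhibitory receptor of differentiated lymphocytes, was 3.90-fold lower. The others were the protease inhibitor Ctla2a (4.5-fold), the transcription factor Npas4 (4.33-fold), the enkephalin precursor Penk (4.14-fold), the lectin Lgals3 (3.84-fold) and the chemokine Ccl5 (3.37-fold). Quantile normalization gave smaller log2 differences for S100a4 (-2.83), Gpr15 (-2.40), Itgae (-2.16), S100a6 (-2.04), Npas4 (-1.52), Ctla2a (-1.48), Penk (-1.45) and Gzmb (-1.39), all still past the threshold. Ccl5 had the largest standard error of these genes (0.30), and its adjusted p of 0.0285 became 0.0814 when every probe set was tested, 0.0768 with the replicate block and 0.153 after quantile normalization. Its adjusted p was 0.125 and 0.0881 without Batf+/+ array 1 or 2, and 0.0831 and 0.107 without Batf-/- array 1 or 2.

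The 12 genes with the largest increases rose between 2.13-fold and 6.33-fold. Plac8 had the largest increase, 6.33-fold (log2 difference 2.66 ± 0.37 SE, limma adjusted p = 0.0097). Gbp2b, an interferon-inducible guanylate-binding protein, rose 4.06-fold (2.02 ± 0.12, adjusted p = 0.00013), and Vdr, the vitamin D receptor, rose 3.71-fold (1.89 ± 0.11, adjusted p = 0.00013). Pparg, a nuclear receptor known from Treg cells of adipose tissue, rose 2.56-fold (1.36 ± 0.15, adjusted p = 0.0032). The gap junction protein Gja1 rose 3.78-fold, with its 6 probe sets between 0.33 and 2.91, and the desmosomal protein Dsp rose 2.37-fold, with its 3 probe sets between -0.12 and 1.93. The kallikrein Klk1b27 (3.13-fold), the Nodal co-receptor Tdgf1 (2.88-fold), the amino acid transporter Slc43a1 (2.46-fold), the lubricating proteoglycan Prg4 (2.38-fold), the protease inhibitor Stfa3 (2.38-fold) and the motor protein Myo6 (2.13-fold) completed the group. Plac8 spread widely over the Batf-/- arrays (0.91 SD), and its adjusted p was 0.0560 without Batf+/+ array 1, 0.05001 without Batf+/+ array 2 and 0.0738 after quantile normalization, which also took Stfa3 to 0.30.

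**Figure D1:**
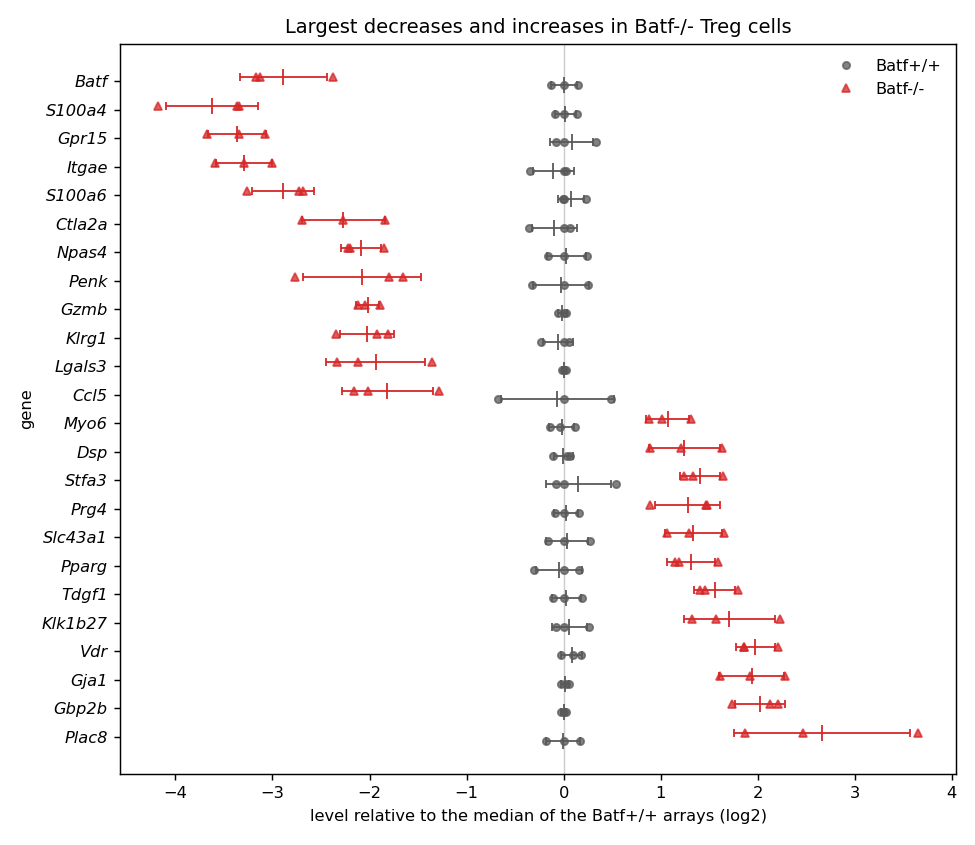
Level of the 12 genes with the largest decreases and the 12 with the largest increases in Batf-/- Treg cells, on a log2 axis relative to the median of the Batf+/+ arrays; circles are the 3 Batf+/+ arrays, triangles the 3 Batf-/- arrays, vertical ticks the means and horizontal bars ±1 SD. Only called genes whose arrays do not overlap between the genotypes could be chosen, so the separation in every gene shown follows from that choice. Mean log2 differences run from -3.64 for S100a4 to 2.66 for Plac8.

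Of 18 measured markers of Treg cells in non-lymphoid tissues, 6 fell and 1 rose (11 and 3 adjusted over the list alone), with a median log2 difference of -0.46. The camera test of the list gave an adjusted p = 1.29e-11, and an adjusted p = 0.0803 with an estimated correlation. Itgae, Gzmb and Klrg1 fell most, and Rora, an orphan nuclear receptor, was 2.07-fold lower (log2 difference -1.05 ± 0.10 SE, limma adjusted p = 0.00148, with its 9 probe sets between -1.83 and -0.01). Ccr2, a receptor for inflammatory chemokines, was 2.09-fold lower, with its 4 probe sets between -1.86 and -0.24, and Cd200r1, an inhibitory receptor named here after its value was seen, was 2.25-fold lower. Pparg was the member that rose. Gata3, a transcription factor of Th2 and tissue Treg cells, had a log2 difference of -0.33 ± 0.14 (adjusted p = 0.626), and Il10, an inhibitory cytokine, one of 0.88 ± 0.30 (adjusted p = 0.396), which became 0.0307 with the replicate block. With that block 9 members were lower and 2 higher past the threshold, where Fgl2 (log2 difference -1.05, adjusted p 0.0529 without the block and 0.0448 with it), Il9r (-0.46, 0.154 and 0.0263) and Nfil3 (-0.94, 0.579 and 0.0193), named after their values were seen, were the lower ones added and Il10 the higher one. Fgl2 was also lower past the threshold after quantile normalization (0.0456), with array weights (0.0140) and without Batf-/- array 1 (0.0219) or 2 (0.0326). Tnfrsf9, named after its value was seen, was lower with array weights (0.0396).

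Of 27 measured effector Treg genes 9 fell and 1 rose (14 and 3 adjusted over the list alone), with a median log2 difference of -0.24. The camera test of the list gave an adjusted p = 1.84e-15, and an adjusted p = 0.269 with an estimated correlation. Besides S100a4, S100a6 and Lgals3, the activation marker Cd83 was 2.48-fold lower (log2 difference -1.31 ± 0.09 SE, limma adjusted p = 0.000202). The costimulatory receptor Icos was 2.09-fold lower (-1.07 ± 0.10, adjusted p = 0.00153), and the inhibitory receptor Pdcd1 was 2.06-fold lower (-1.04 ± 0.10, adjusted p = 0.00138). Prdm1, which encodes the transcriptional repressor Blimp-1, was 1.72-fold lower (-0.78 ± 0.12, adjusted p = 0.0132). Irf4, the partner of Batf at composite DNA elements, was the member that rose, by 1.46-fold (0.54 ± 0.10, adjusted p = 0.0454), although 0 of its 2 probe sets, at 0.31 and 0.78, passed the threshold when every probe set was tested. With the replicate block 2 members were higher, Irf4 and Il10, and with array weights Tnfrsf9 was lower (adjusted p = 0.0396). Prdm1 had adjusted p values of 0.0724, 0.0639 and 0.0510 without Batf+/+ array 1, 2 or 3 and of 0.0616 after quantile normalization. Irf4 had adjusted p values of 0.188, 0.154 and 0.0848 without Batf+/+ array 1, 2 or 3, of 0.122 and 0.131 without Batf-/- array 1 or 3, of 0.0509 with equal array medians and of 0.115 after quantile normalization.

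The genes that define Treg identity divided. Cells of both genotypes were isolated by a reporter expressed with Foxp3, so the gate itself may in part set their Foxp3 level. Foxp3 had a log2 difference of -0.12 ± 0.08 (SE, limma adjusted p = 0.892, 95% interval -0.30 to 0.05), Il2ra, the high-affinity interleukin 2 receptor chain, one of 0.21 ± 0.07 (adjusted p = 0.394), Ctla4, an inhibitory receptor, one of -0.25 ± 0.17 (adjusted p = 0.923), and Ikzf2, which encodes Helios, one of -0.51 ± 0.10 (adjusted p = 0.0526), which passed with array weights (-0.59, adjusted p = 0.0140). Of 20 measured core identity genes 4 fell and 1 rose (7 and 3 adjusted over the list alone), with a median of -0.15. Those that fell were Penk, Cd83, the semaphorin receptor Nrp1 (2.16-fold lower, -1.11 ± 0.09, adjusted p = 0.00059) and Ttc39c (2.60-fold lower, with its 3 probe sets between -2.99 and -0.38). Plagl1, a zinc finger protein named here after its value was seen, rose by 0.52 ± 0.10 on the log2 scale (adjusted p = 0.0432). Its adjusted p was 0.0786 to 0.167 without Batf+/+ array 1, 2 or 3 or Batf-/- array 1 or 2, 0.244 after quantile normalization and 0.873 without probe sets whose suffix marks shared sequence. The 3 probe sets lay between -0.05 and 1.24. Without Batf+/+ array 3 Itgb8, named after its value was seen, was lower (adjusted p = 0.0302). The camera test of the list gave an adjusted p = 0.000174, and an adjusted p = 0.269 with an estimated correlation.

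Resting lymphoid Treg genes had slightly higher values, with 16 of 20 measured members above 0, a median log2 difference of 0.07 and 0 members past the threshold over all genes or adjusted over the list alone. Ccr7, the receptor for entry into lymph nodes, had a log2 difference of 0.25 ± 0.11 (SE, limma adjusted p = 0.684). The camera test gave an adjusted p = 0.0130, and an adjusted p = 0.50 with an estimated correlation. Its adjusted p was 0.148 without Batf+/+ array 2 and 0.416 without Batf-/- array 1. The median was 0.11 after quantile normalization, 0.12 without Batf+/+ array 1 and 0.13 without Batf-/- array 3, where Il7r, named after its value was seen, was higher past the threshold (adjusted p = 0.0277).

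Receptors that direct Treg cells to tissues were among the genes that fell most, and 0 of them rose. Of 27 measured trafficking receptors 5 fell (9 adjusted over the list alone), with a median log2 difference of -0.21. These were Gpr15, Itgae, Ccr2, the integrin chain Itgb1 (2.12-fold lower, log2 difference -1.08 ± 0.08 SE, limma adjusted p = 0.00033, with its 6 probe sets between -2.55 and -0.01) and, named after its value was seen, the chemokine receptor Cxcr6 (3.31-fold lower, -1.73 ± 0.21, adjusted p = 0.00567). The values of the skin and mucosal receptors Ccr4, Ccr6 and Ccr8 were -0.58 ± 0.18 (adjusted p = 0.311), -0.27 ± 0.16 (adjusted p = 0.887) and -0.46 ± 0.18 (adjusted p = 0.517), and that of Ccr4 passed the threshold with the replicate block (adjusted p = 0.0473). Cxcr3, a chemokine receptor also in the Th1 list, had a log2 difference of -1.06 ± 0.30 (adjusted p = 0.249), which was -1.49 (adjusted p = 0.000940) without Batf-/- array 3. With array weights Ccr9 (0.0455) and Ccr10 (0.0448) were lower past the threshold. These 3 were named after their values were seen. The camera test of the list gave an adjusted p = 1.4e-10, and an adjusted p = 0.0505 with an estimated correlation. The median was -0.14 without Batf+/+ array 3, -0.13 without Batf-/- array 1 and -0.12 without Batf-/- array 2.

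Genes of helper T cell lineages moved in both directions. Of 11 measured Th1 genes, 2 fell (4 adjusted over the list alone), both chains of the interleukin 18 receptor: Il18r1 was 2.47-fold lower (log2 difference -1.31 ± 0.10 SE, limma adjusted p = 0.00059) and Il18rap 2.01-fold lower (-1.01 ± 0.14, adjusted p = 0.0103). The Th1 list had a median of -0.11 and a camera adjusted p = 0.0023, with an adjusted p = 0.308 with an estimated correlation. Its median was -0.18 without Batf+/+ array 1 or Batf-/- array 3 and -0.07 without Batf+/+ array 2, and Cxcr3 was lower past the threshold without Batf-/- array 3. Of 12 measured genes of follicular helper and follicular Treg cells, 3 fell and 2 rose (5 and 2 adjusted over the list alone), with a median of -0.22. Il21, the cytokine of follicular helper cells, rose 2.12-fold (1.09 ± 0.10, adjusted p = 0.00138), with its 2 probe sets at 0.32 and 1.86 and only 1 of them past the threshold when every probe set was tested, while the signalling adaptor Sh2d1a was 1.95-fold lower and Pdcd1 2.06-fold lower. Tox2, a transcription factor, was 2.22-fold lower, but its 2 probe sets gave -2.09 and -0.21, and the call rested on the former, since its adjusted p was 0.860 without probe sets whose suffix marks shared sequence. The inhibitory receptor Btla, named after its value was seen, rose by 0.44 ± 0.08 (adjusted p = 0.0285), with an adjusted p of 0.0781 to 0.154 without Batf+/+ array 1, 2 or 3 or Batf-/- array 2 or 3 of 0.176 after quantile normalization and of 0.0880 when every probe set was tested. With array weights 5 members were lower, by Bcl6 (adjusted p 0.0476) and Sostdc1 (0.0249), named after their values were seen, and Sostdc1 was also lower with the replicate block (0.0292) and without Batf+/+ array 1 (0.0108). The camera test of the follicular list gave an adjusted p = 2.48e-05, and an adjusted p = 0.269 with an estimated correlation. Of 9 measured Th17 genes, Rora and Ahr, a ligand-activated transcription factor (-0.57 ± 0.08, adjusted p = 0.00998, with its 2 probe sets at -1.04 and -0.10 and neither past the threshold when every probe set was tested), fell and Il21 rose, the same numbers as adjusted over the list alone, and the list had a camera adjusted p = 0.308. Of 11 measured Th2 genes 0 passed over all genes, with 3 lower and 2 higher adjusted over the list alone, a median of -0.07 and a camera adjusted p = 0.113, while Ccr4 (adjusted p = 0.0473) and, named after its value was seen, the receptor chain Il17rb (0.0360) passed with the replicate block. Il17rb was also lower past the threshold with equal array medians (0.0478) and without Batf-/- array 2 (0.0213). Il4, named after its value was seen, was lower with array weights (0.0395) and without Batf-/- array 1 (0.0402). Without Batf+/+ array 2 the adjusted p of Il18rap was 0.0590 and that of Ahr 0.0631. Quantile normalization took Il21 to 0.105, Il18rap to 0.0551 and Ahr to 0.0748, and without Batf+/+ array 3 or Batf-/- array 2 the Th2 list had a camera adjusted p of 0.0263 or 0.0494. After quantile normalization the Th2 list had one of 0.0383, and its median was -0.13 without Batf+/+ array 1 and -0.12 without Batf+/+ array 3.

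**Figure D2:**
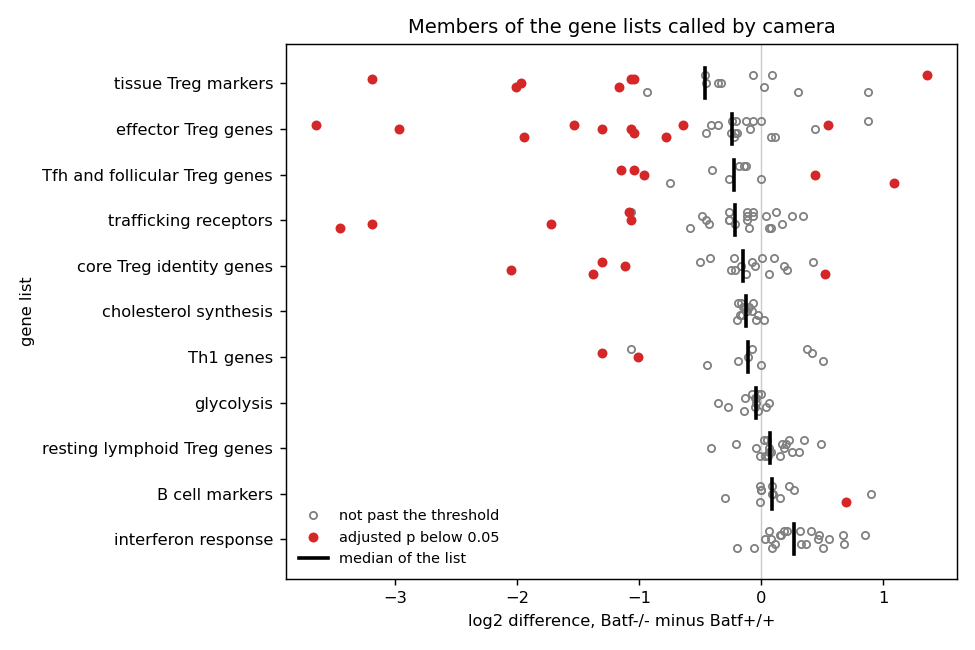
Log2 difference, Batf-/- minus Batf+/+, of each measured member of the 11 gene lists called by camera with its preset correlation; filled points have a limma adjusted p below 0.05 over all genes, open points do not, and the black bar is the list median. Medians run from -0.46 for tissue Treg markers to 0.27 for the interferon response, and 0 of the 11 lists is called with an estimated correlation.

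Of 22 measured interferon response genes 20 lay above 0, with a median log2 difference of 0.27 and 0 past the threshold over all genes (5 higher adjusted over the list alone). The camera test gave an adjusted p = 4.24e-07, and an adjusted p = 0.50 with an estimated correlation. The guanylate-binding protein Gbp2 had a log2 difference of 0.67 ± 0.14 (SE, limma adjusted p = 0.0689) and the immunity-related GTPase Igtp one of 0.51 ± 0.10 (adjusted p = 0.0539), both named after their values were seen. Outside the list, the interferon-inducible chemokine Cxcl10, also named after its value was seen, was lower (-1.51, adjusted p = 0.0131). Its adjusted p was 0.166 after quantile normalization and 0.0635 and 0.0583 without Batf+/+ array 1 or Batf-/- array 2. Batf+/+ array 2 stood apart, with a list mean of 0.42 against -0.05 on each of the other Batf+/+ arrays and 0.34, 0.29 and 0.57 on the Batf-/- arrays. Without it the median was 0.51 and 2 members, the antiviral proteins Oasl1 (0.68, adjusted p = 0.0347) and Oasl2 (1.14, adjusted p = 0.0302), were higher past the threshold. The median was 0.17 without Batf+/+ array 3 and 0.15 without Batf-/- array 3, and Gbp2 was higher past the threshold without Batf-/- array 2 (adjusted p = 0.0388). The list median was 0.10 after quantile normalization and 0.11 with array weights, where the camera adjusted p was 0.021. Those weights were largest for Batf+/+ array 2 (2.21), the array that stood apart.

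Metabolic genes differed little. The 15 measured genes of cholesterol synthesis had 14 values below 0, a median log2 difference of -0.12 and 0 members past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.00113, adjusted p = 0.436 with an estimated correlation). The 14 measured glycolysis genes had 11 values below 0, a median of -0.05 and 0 members past the threshold, or 1 lower adjusted over the list alone (camera adjusted p = 0.0307, adjusted p = 0.476 with an estimated correlation). The cholesterol list had an adjusted p of 0.0542 without Batf-/- array 3, and a median of -0.07 after quantile normalization. The glycolysis list had one of 0.122 and 0.0527 without Batf+/+ array 1 or 2, of 0.0622 and 0.161 without Batf-/- array 1 or 2, and of 0.0562 without probe sets whose suffix marks shared sequence, and its median was -0.08 without Batf-/- array 3.

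Genes of proliferation, survival and T cell receptor signalling were not called as lists. The 32 measured cell cycle genes had a median log2 difference of 0.01 with 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.328), although without Batf-/- array 2 the list had an adjusted p of 0.0258 and a median of 0.05. The median turned to -0.01 without Batf+/+ array 2 and to -0.04 without Batf-/- array 3, where Ccnb2, named after its value was seen, was lower (adjusted p = 0.0470). Of 17 measured apoptosis regulators, Fasl, the ligand of the death receptor Fas, fell by 0.91 on the log2 scale (SE 0.15, limma adjusted p = 0.0228), and 1 higher and 1 lower passed adjusted over the list alone (camera adjusted p = 0.381). Without Batf-/- array 3 Bcl2l11, named after its value was seen, was higher (adjusted p = 0.0291). Of 15 measured genes of the T cell receptor response Irf4 alone passed, 2 were higher adjusted over the list alone, and the camera adjusted p was 0.282. The 21 measured TNF receptor and NF-kB genes had a median of -0.06 and 0 past either threshold (camera adjusted p = 0.101). This list had an adjusted p of 0.00379 without Batf+/+ array 3 and of 0.0458 after quantile normalization. Its median was 0.01 without Batf+/+ array 1, -0.14 without Batf+/+ array 3 and -0.04 with array weights, where Tnfrsf9, named after its value was seen, was lower (adjusted p = 0.0396). Of 21 measured AP-1 and IRF factors Batf fell and Irf4 rose (1 lower and 2 higher adjusted over the list alone), with a median of 0.16, a mean of -0.03 and a camera adjusted p = 0.241. Batf is the deleted gene, so its fall follows from the genotype and pulls the mean down. Of the 21 values 14 lay above 0, and the list was not tested without Batf. The list median was 0.06 without Batf+/+ array 3 and after quantile normalization, and 0.07 without Batf-/- array 1 and with array weights. Fasl had adjusted p values of 0.0868, 0.0651 and 0.0524 without Batf+/+ array 1, 2 or 3, of 0.0681 without Batf-/- array 2 and of 0.0601 after quantile normalization. Neither of its 2 probe sets passed when every probe set was tested (smallest adjusted p 0.0814). With the replicate block the T cell receptor response had 2 higher and 1 lower, by Cd200 (adjusted p 0.0455) and Nr4a2 (0.0343), and the AP-1 and IRF factors 2 higher and 2 lower, by Irf8 (0.0306, and 0.0389 without Batf-/- array 2) and Nfil3 (0.0193), named after their values were seen. Irf4 lost its call without 5 of the 6 arrays, at adjusted p values of 0.0848 to 0.188.

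Markers of other cells that the sorted population could hold were measured beside these groups. Of 13 measured B cell markers, Ly6d rose by 0.69 ± 0.13 on the log2 scale (SE, limma adjusted p = 0.0449), the same 1 gene as adjusted over the list alone, with a median of 0.09 and a camera adjusted p = 0.0336, or an adjusted p = 0.511 with an estimated correlation. The list mean was 0.37 on Batf-/- array 3 against 0.07 and 0.10 on Batf-/- arrays 1 and 2, and its adjusted p was 0.155 without Batf-/- array 3, 0.127 and 0.0527 without Batf+/+ array 1 or 2, and 0.0628 with array weights. The median was 0.02 without Batf+/+ array 1, 0.15 without Batf-/- array 1 and 0.04 without Batf-/- array 3, where Cd22, named after its value was seen, was higher (adjusted p = 0.0461). Monocyte and macrophage markers had a mean of 0.34 on Batf-/- array 3 and between -0.14 and 0.14 on the other arrays, with 0 of 15 past the threshold (camera adjusted p = 0.485). Among 6 CD8 T cell markers Cd160, an activating receptor of cytotoxic cells (-0.60 ± 0.09, adjusted p = 0.0199, with its 4 probe sets between -0.86 and -0.09), and Ccl5 fell, also adjusted over the list alone, with a median of 0.02, a mean of -0.27 and a camera adjusted p = 0.308. That median was 0.06 without Batf+/+ array 2 and 0.07 without Batf-/- array 2, but -0.03 with array weights and -0.01 without Batf-/- array 3. Among 11 conventional CD4 T cell genes Il21 rose, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.241), and Il4 was lower with array weights (adjusted p = 0.0395) and without Batf-/- array 1 (0.0402). Among 7 NK cell markers 0 passed over all genes and 1 was higher adjusted over the list alone, with a median of -0.01, a mean of 0.12 and a camera adjusted p = 0.308. The NK median was 0.04 without Batf+/+ array 1 or Batf-/- array 3 and -0.05 without Batf+/+ array 3. Among 11 dendritic cell markers 0 passed over all genes and 1 was higher and 1 lower adjusted over the list alone (camera adjusted p = 0.189), and Irf8 was higher with the replicate block (adjusted p = 0.0306) and without Batf-/- array 2 (0.0389), while Ccr9, named after its value was seen, was lower with array weights (0.0455). Markers of plasma cells (6 measured, camera adjusted p = 0.328), neutrophils (9, 0.396), erythroid cells (6, 0.947), platelets (5, 0.196) and lymph node stroma (8, 0.556) had 0 members past either threshold. Without Batf+/+ arrays 1, 2 or 3 or Batf-/- arrays 2 or 3, in turn, the adjusted p of Ly6d was 0.198, 0.180, 0.0564, 0.148 and 0.0871. It was 0.121 when every probe set was tested. That of Cd160 was 0.0930, 0.0555, 0.0732, 0.0600 and 0.0639 without Batf+/+ arrays 1, 2 or 3 or Batf-/- arrays 1 or 3. Quantile normalization ended the calls of Ly6d (0.14), Cd160 (0.202) and Ccl5 (0.153). The last was also lost with the replicate block (0.0768) and without Batf+/+ array 1 or 2 or Batf-/- array 1 or 2 (0.0831 to 0.125).

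Signs of RNA quality overlapped between the genotypes. The difference between the 3' and 5' control probe sets of Gapdh was 0.02 ± 0.04 in Batf+/+ and 0.03 ± 0.05 in Batf-/- arrays on the log2 scale (SD, n = 3, exact two-sided permutation p = 1), and for beta-actin the exact p was 0.4, where 0.1 is the smallest p that 3 arrays against 3 allow. Control probe sets were centred on the Batf+/+ arrays as well. These values can therefore show a difference between genotypes, but not how intact the RNA was in either. The 11 measured housekeeping genes had a median log2 difference of 0.03 with 0 past either threshold (camera adjusted p = 0.538), and the 5 sex-linked genes one of 0.09 with 0 past either threshold (camera adjusted p = 0.247), or 0.06 without Batf+/+ array 3 and with array weights. The 18 measured genes of the dissociation stress response, the early genes induced while tissue is made into single cells, had 0 past either threshold (camera adjusted p = 0.247) but varied between arrays of the same genotype. Their means were -0.01, 0.66 and -0.59 on Batf+/+ arrays 1, 2 and 3 and 0.88, 0.04 and -0.38 on Batf-/- arrays 1, 2 and 3. Without Batf+/+ array 2 or Batf-/- array 3 this list had a camera adjusted p of 0.00248 or 7.16e-05.

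Among the 20 measured genes that neighbour Batf on its chromosome, 10 on each side, 0 passed the threshold in limma and 3 passed it before adjustment. These were Jdp2, an AP-1 factor (log2 difference 0.21 ± 0.08 SE, limma adjusted p = 0.466), Tgfb3 (0.36 ± 0.16, adjusted p = 0.630) and Irf2bpl (-0.17 ± 0.07, adjusted p = 0.580), named after their values were seen. Over all 18193 genes, 1399 had an unadjusted limma p below 0.05. The median over the 20 genes was 0.029, at percentile 82.4 of 10000 random lists of the same size.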

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

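All tests of explanations below were chosen after the result they bear on had been seen, except the count of other splits of the arrays.

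Probe sets with no gene listed stood outside the comparison by gene, and 6 of these 9160 were higher in Batf-/- than in Batf+/+ cells past the threshold when every probe set was tested, with 19 lower. This signal lies in data that the comparison did not use. Changed probe sets made up 0.273% of those with no gene listed and 0.604% of those with 1 gene. Their identity was not analysed here, and no biological explanation was tested.

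The real split of the 6 arrays into 3 and 3 gave 208 genes and was 1 of 10 splits, of which the highest other gave 0, including the other splits that part all 3 same-numbered pairs. So few splits cannot give a share below 0.05. Each other split also mixes the genotypes, so genotype differences add to its residual spread and hold its count down. Those counts therefore do not show what arrays without such differences would give.

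Among the 43 measured members of the effector and tissue Treg lists, 15 fell and 2 rose. A smaller share of effector cells in the Batf-/- population, with no change within cells, could lower these members together. It would not raise the 2 that rose, Irf4 and Pparg, if effector cells here held more of both. That is known only from list membership, since the centred values hold no levels, and Irf4 lost its call in several alternatives. The rise of these 2 therefore does not decide the question. For the 15 that fell a smaller share stays open: the resting list had a median log2 difference of 0.07 and an unadjusted camera p of 0.193 with an estimated correlation, and shares of cells were not measured. Regulation of these genes by Batf within each cell stays equally open and was not tested.

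The B cell markers were weighed as signs of other cells in the sorted population, from which a gate on CD4 and human CD2 would remove B cells and most myeloid cells. On Batf-/- arrays 1 and 2 Ly6d and Cd22 lay above the Batf+/+ arrays by 0.58 and 0.47 and the median over the 11 other markers was 0.03, which leaves open whether more B cells were present there. On Batf-/- array 3 the B cell markers lay 0.193 above the other Batf-/- arrays in the median, 10 of 13 were higher there than on both of those, and so were 14 of 15 monocyte and macrophage markers (median 0.36) and 41.1% of all genes, which is consistent with a small number of other cells on that array. A deviation shared by the arrays numbered 3 stays open as well: on Batf+/+ array 3 the B cell markers lay 0.124 above the other Batf+/+ arrays in the median, with 8 of 13 higher there than on both, as were 11 of 15 monocyte and macrophage markers (median 0.18) and 43.1% of all genes. The spike-in means of both arrays stood apart too (hybridisation 0.42 and 0.35, polyA -0.36 and -0.63 on the Batf+/+ and Batf-/- array), and expression of Ly6d or Cd22 by Treg cells themselves was not tested.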

How the results depend on the processing

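The alternatives robust variance without a trend and camera with array weights, and the count of neighbouring pairs in each alternative, were chosen after the data had been seen, and the others before. Batf kept its direction and its call in every alternative (log2 differences -3.15 to -2.02). Of 319 values of named genes with all arrays kept, 302 kept their side of the threshold, 14 lost it and 3 gained it. Of 318 with an array left out, 288 kept it and 30 lost it. Of the 43 called genes 34 stayed called whichever array was left out. When every probe set was tested, 5 of the 43 had no probe set past the threshold, Ccl5, Irf4, Ahr, Fasl and Ly6d. The 3 genes that gained a call were Ikzf2 with array weights and Il10 and Ccr4 with the replicate block. No called gene or list reversed, and of 232 values of uncalled lists 12 had the other direction. Of the 208 genes, 206 remained with equal array medians, 205 with array weights, 197 without suffixed probe sets and 207 with robust variance. Quantile normalization gave 81 genes, 23 higher and 58 lower, and kept 79 of the 208. It forces the wider spread of the Batf-/- arrays and the narrower one of the centred Batf+/+ arrays onto 1 distribution, so its smaller differences follow in part from its construction. The replicate block gave 91 higher genes and 202 lower, and 202 of the 208 remained. The cause of its higher count was not tested. It ended the call of Ccl5, added Il10 and Ccr4, and changed no other call of a list or of a gene in the naming rule. Leaving out 1 array gave 105 to 192 genes, 31 to 51 higher and 73 to 141 lower, with fewer arrays in the fit. Across the alternatives fitted by gene the share of lower genes stayed between 66.7% and 78.9%.

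With an estimated correlation 0 of the 11 called lists passed: adjusted p was 0.0803 for tissue Treg markers, 0.269 for effector genes, 0.50 for resting genes, 0.269 for core identity genes and 0.0505 for trafficking receptors. By fry 5 of the 11 passed, and the resting list had 0.320. The resting list ranged from 0.000125 to 0.416 with an array left out. For trafficking receptors the estimated correlation was 0.00021, below the preset 0.01, yet the unadjusted camera p rose from 1.35e-11 to 0.00163. This argues against a higher correlation as the cause in that list. The uncalled Th2 list, with an estimate of -0.0074, also rose, from 0.0472 to 0.106. The other called lists had estimates of 0.043 to 0.60, and correlation stays open as a cause there. The forms of camera also differ in degrees of freedom, which with an estimated correlation are only those left by the 6 arrays. Fewer degrees of freedom raise the p-value of the same statistic, whatever the correlation. How much of these differences they account for was not tested, nor were other causes. Leaving out 1 array called 9 to 13 lists, and 170 of 186 values kept their side, 10 lost it and 6 gained it. Filters on dim genes, a variance trend and the choice of the brightest probe set were not run, since the centred values hold no levels, and what signal over background limits is not known.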

Other observations

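The tests of neighbouring genes below were chosen after the result had been seen.

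Further genes changed outside the lists and were named after their values were seen. The inflammatory cytokine Il18 was 2.70-fold lower (log2 difference -1.43 ± 0.19 SE, limma adjusted p = 0.00762). The cystatin Cst7, a protease inhibitor of cytotoxic cells, was 3.04-fold lower (-1.60 ± 0.10, adjusted p = 0.000164), and Ctla2b, a relative of the protease inhibitor Ctla2a, was 3.33-fold lower. The receptor tyrosine kinase Axl was 1.53-fold lower (-0.62 ± 0.07, adjusted p = 0.00567), and the transcription factor Myb rose 1.91-fold (0.94 ± 0.12, adjusted p = 0.00645). After quantile normalization the adjusted p was 0.0603 for Il18, 0.0601 for Axl and 0.0574 for Myb, and without probe sets whose suffix marks shared sequence Axl had a log2 difference of -1.24 (adjusted p = 0.000161), its other probe set being at 0.01.

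Changed genes lay beside each other on chromosomes more often than shuffled calls did. Of 208 changed genes, 6 adjacent pairs changed in the same direction, against a median of 1 in 10000 shuffles of the calls over 18143 placed genes (permutation p = 0.0029). The pairs that fell were Il18r1 and Il18rap, Poglut2 and Bivm, Gzmc and Gzmb, Gpr15 and Cldnd1, and Nrp1 and Itgb1, and the pair that rose was Lad1 and Tnnt2, where Il18rap, Poglut2, Bivm, Gzmc and Cldnd1 each lost the call without at least 1 of the 6 arrays (adjusted p of 0.0509 to 0.113). Quantile normalization ended the calls of Poglut2 (0.182), Bivm (0.0790), Gzmc (0.319) and Il18rap (0.0551), which are members of 3 of the 6 pairs. The 1 probe set of Gzmc had an adjusted p of 0.0805 when every probe set was tested, and the 3 probe sets of Tnnt2 lay between 0.001 and 1.19 and those of Cldnd1 between -1.13 and -0.15. Probe sets whose suffix marks shared sequence are argued against as the whole cause, since 6 pairs remained without the suffixes _x_at and _s_at (permutation p = 0.0024), and 4 when _a_at, which marks transcripts of 1 gene, was left out as well (permutation p = 0.0343). Shared sequence between probe sets without a suffix, as could occur in the related genes Gzmb and Gzmc, was not tested. Across the other alternatives fitted by gene there were 3 pairs (without Batf+/+ array 1) to 12 (with the replicate block), at permutation p of 0.0066 or below, with 4 pairs without Batf+/+ array 2 and after quantile normalization, 8 without Batf-/- array 2, 10 with equal array medians and 11 with array weights.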
